A study of Ginkgo biloba with 15 samples.

How the data were processed

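Embryos of Ginkgo biloba, a gymnosperm tree, were sampled in 2 months of 2015 (September, November) and again in February 2016, per the labels' protocols. Total RNA was extracted with a plant RNA kit and made into Illumina libraries, per the same protocols. The 15 libraries comprised 6 mRNA libraries, 2 per month, and 9 small-RNA libraries, 3 per month. Libraries were grouped by the collection month in their labels, and every column of per-sample values was used. No label says whether libraries of 1 month came from separate trees or seeds. The p-values therefore measure only the spread between these libraries, which may be technical.

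The deposited mRNA table gives FPKM, the fragments counted on a gene scaled by its length and the depth of the library, for each gene and library, per the file headers. It holds 43690 gene models on 8272 scaffolds, of which 41840 carry the identifier of an annotation and 1850 are models added by the authors. The submitters' processing notes name CASAVA 1.8, TopHat2 2.0.12, HTSeq 0.6.1 and Bowtie, without their roles. The genome build, the annotation and the use of strand in counting are not given in the sources used here, and coordinates are those of the deposited table. The table pairs identifiers with positions and not with gene names or descriptions. The 30 gene lists in the plan were defined by words in gene descriptions, so they could not be applied and no list was tested. For the same reason at most 2 genes that rose and 2 that fell are named by identifier.

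The product of FPKM and listed gene length was a whole multiple of a single step per library, within a tolerance of 0.05 of a read, for 98.74% to 98.81% of values and 97.95% to 98.07% of values above 0. The 626 genes with a value that was not whole were all added models. Dividing by the step recovered 14508997 to 19641543 reads per library. Recovered reads served as depth and in tests with DESeq2 and edgeR, which left those 626 genes out.

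The deposited small-RNA table gives raw read counts per miRNA name, per the file headers, with no normalization. It lists 361 names, 342 known and 19 predicted. Known names carry the prefix of the plant species in which the sequence was catalogued. A total of 149 names held the same 9 counts as another name, so that a read could be listed under several names and 252 rows of counts were distinct. Totals of these counts were 90008 to 1269029 per library, and they are counts listed under miRNA names rather than the depth of the whole library. A count of 0 allows an abundance of up to 3 counts, which is 2.36 to 33.3 in CPM (counts scaled by the library total) depending on the library. These limits cover counting error only.

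Statistics were computed in R 4.3.3. The design of each test, the named genes and most alternatives were fixed before the data were examined. For mRNA, the plan named edgeR for counts and limma for FPKM, and the deposited FPKM called for limma 3.58.1. A linear model with 1 coefficient per month and a mean-variance trend was fitted to log2(FPKM + 1) of all 6 libraries. It used the 22947 genes with at least 1 FPKM in at least 2 libraries and left 3 residual degrees of freedom. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. For miRNA, edgeR 4.0.16 was used with TMM factors and its quasi-likelihood test on the 145 names with at least 10 counts in at least 3 libraries. Family counts were the sums over names with the same miR number, tested with the library sizes of the name-level fit. Of 65 families, 35 passed the same minimum, including 20 of the 36 families fixed for comment. All p-values were adjusted by the Benjamini-Hochberg method within a comparison, with a threshold of 0.05.

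Gene naming followed a fixed rule. In each successive comparison, genes past the threshold with non-overlapping months and a mean of at least 5 FPKM in the higher month were ranked by fold change. The requirement of a description could not be met, and the gene with the largest rise and the gene with the largest fall were named. The 3 most abundant genes and the 5 most abundant miRNA names by mean share of counts were to be named too. The genes are given by position. Families past the threshold are named. Other families and names were chosen after their values were seen.

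Titles number the libraries within each month. Among small-RNA libraries, deviations from the month's mean were correlated across names between libraries of the same number, at 0.37 to 0.9 for all 9 such pairs. Between libraries of other numbers the correlation was −0.84 to 0.8, and 7 of the 9 libraries correlated best with their own number in both other months. February 2 correlated more with September 1 (0.8) and November 1 (0.71) than with September 2 (0.46) and November 2 (0.37). The rule set for pairing was a correlation above 0.1 in every pair. The numbers were therefore treated as pairing the small-RNA libraries, on the evidence of these values and not of a label. Results within pairs rest on this reading. By itself the rule cannot tell pairing of numbers 1 and 2 from a library standing apart in each month. Such a library tends to put the others of its month on the same side of the mean. Mismatched libraries numbered 1 and 2 also passed 0.1. These were September 1 with November 2 (0.3) and February 2 (0.8), and November 1 with February 2 (0.71). September 2 with November 1 (0.13) and February 1 (0.18) also passed, but November 2 with February 1 (0) did not. The fit with the number as a block is given beside a miRNA result where it changes the call. The block lowered edgeR's common dispersion from 1.2 to 0.325. No library was a duplicate of another. Chi-square per degree of freedom between libraries of a month was 17.62 to 60.5 for recovered mRNA reads and 81.37 or more for small-RNA counts.

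The fits were tested on simulated data. Counts were drawn for 22359 genes at the real depths, with 200 genes changed in February. For February against September, limma called 2%, 64%, 88% and 94% of genes changed 2-, 4-, 8- and 16-fold, with 9 unchanged genes called. For February against November it called 4%, 66%, 88% and 94%, with 11 unchanged genes. Far fewer genes were changed there than the 61% called between September and February in the data. The adjusted threshold was therefore stricter in the simulation, and its shares may understate recovery in the data. For 145 miRNA names with 30 changed in February, over 20 repeats of February against September, edgeR called 0% of 4-fold and 2.33% of 8-fold changes without the block. With the block it called 29.7% and 67%, with a mean of 0.85 unchanged names called per repeat, against 0 without it. These counts were drawn with number effects fitted to the data and the dispersions of the blocked fit. The gain from the block was therefore built in and gives no support to the pairing.

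Alternatives covered the pseudocount, filters on low values, scaling, DESeq2 1.42.0, a fold threshold, fits of only the 2 months compared, the replicate block and leaving out each library in turn. DESeq2 was planned before the data were seen, and its use on recovered reads was decided afterwards. Alternatives chosen after seeing the data were TMM scaling and edgeR for mRNA, leaving out the small-RNA libraries numbered 3, counting identical names once, using the strongest name of a family, and every alternative with the block.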

Results

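Expression was followed in Ginkgo biloba embryos over 3 collection months to describe their development and dormancy. September, November and February were each represented by 2 mRNA libraries and 3 small-RNA libraries. The mRNA libraries held 14508997 to 19641543 recovered reads, and 20260 to 21206 genes reached 1 FPKM in a library. The small-RNA libraries held 90008 to 1269029 counts under miRNA names.

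Libraries of the same month were the most alike in mRNA. The correlation across genes of log2(FPKM + 1) was 0.982 between the September libraries, 0.951 between the November libraries and 0.98 between the February libraries. It was 0.837 to 0.877 between September and November, 0.83 to 0.89 between November and February and 0.716 to 0.746 between September and February, and genes are not independent replicates. Of 22947 genes tested, 16281 (71%) passed the threshold in at least 1 of the 3 comparisons with limma.

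The most abundant genes differed between months. A gene on the minus strand of scaffold 1909 (1900883 to 1902638) held 1158 ± 174 FPKM in September, 11190 ± 2760 in November and 5592 ± 3270 in February (SD, n = 2). Its rise from September to November had a log2 fold change of 3.26 (SE 0.49, limma adjusted p = 0.0056). That call was lost without September 1 (adjusted p = 0.063) or September 2 (adjusted p = 0.083). A gene on the minus strand of scaffold 9952 (171074 to 171784) rose from 219.8 ± 68.4 to 20760 ± 12000 FPKM over the same months, by 6.46 (SE 0.87, limma adjusted p = 0.004). A second gene on the minus strand of scaffold 1909 (631381 to 632201) held 19030 ± 4330 FPKM in September, 835.6 ± 399 in November and 219.7 ± 82 in February. It fell between September and February with a log2 fold change of −6.46 (SE 0.44, limma adjusted p = 0.00016). The 10 most abundant genes took 3.358% to 6.213% of the reads of a library. None of these 3 models overlapped another listed model, and the table names none of their products.

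Between September and November, 3339 genes rose and 3651 fell by limma, 30.5% of those tested. The median absolute log2 fold change of these genes was 1.2. At least 4-fold rises numbered 659 and 4-fold falls 577. The largest rise was that of Gb_16563 on the plus strand of scaffold 2528 (6203698 to 6204465). It was listed at 6.62 FPKM in September 1 and at 0 in September 2, and at 1196.22 and 716.85 FPKM in November, with a log2 fold change of 8.39 (SE 1.02, limma adjusted p = 0.0032). The largest fall was that of the added model Novel01102 on the minus strand of scaffold 4 (329169 to 331181). It stood at 366.45 and 940.96 FPKM in September and at 0.4 and 0.06 FPKM in November, a log2 fold change of −8.92 (SE 0.53, limma adjusted p = 0.00073). Chance gives non-overlapping months for 33.3% of genes with 2 libraries against 2. All 6990 called genes had them, but calling selects for such genes, so this adds no support. The count was 2252 without September 1 and 2027 without September 2. Which direction held more genes depended on the scaling and the tool, since 47.8% of called genes were higher in November with FPKM as deposited, 52.5% with TMM factors, 53.6% with DESeq2 and 56.2% with edgeR on recovered reads.

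Between November and February, 4270 genes rose and 5192 fell by limma, 41.2% of those tested. Rises of at least 4-fold numbered 554 and falls 655. The gene with the largest rise was again Novel01102, which returned to 400.92 and 923.64 FPKM in February, by 8.97 on the log2 scale (SE 0.53, limma adjusted p = 0.00071). Its September and February levels differed by 0.05 (SE 0.53, limma adjusted p = 0.94). Gb_19513, on the plus strand of scaffold 3017 (461067 to 461544), showed the largest fall. It was listed at 3252.73 and 792.32 FPKM in November and at 1.8 and 1.05 FPKM in February, a log2 fold change of −9.39 (SE 0.61, limma adjusted p = 0.00076). In September it stood at 2446.86 and 3531.75 FPKM. Without February 1 the count of 9462 genes became 3995. The excess of falls depended on the scaling, since 45.1% of called genes were higher in February with FPKM as deposited, 52.1% with RLE factors and 42.2% with upper quartile factors.

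Gb_16563, the gene with the largest rise into November, stood at 26.68 and 117.37 FPKM in February, and its log2 fold change from November was −4.02 (SE 1.02, limma adjusted p = 0.022). That call was lost with a pseudocount of 0.1 (adjusted p = 0.12), with DESeq2 (adjusted p = 0.2) and edgeR (adjusted p = 0.055) on recovered reads, and without November 1 (adjusted p = 0.06) or February 1 (adjusted p = 0.14). Over all its alternatives except single left-out libraries the adjusted p was 0.019 to 0.2.

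**Figure D1:**
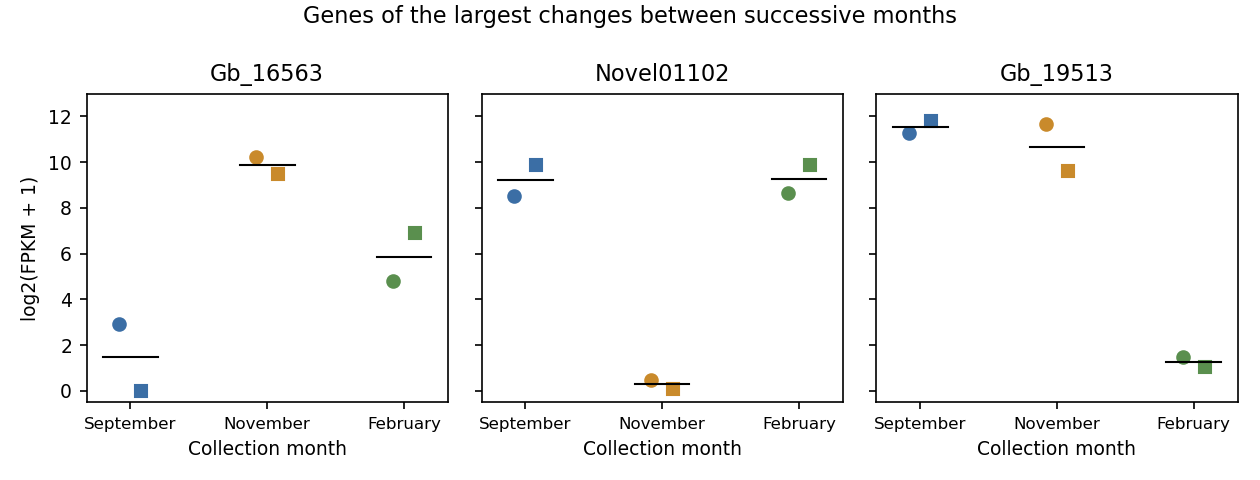
Log2(FPKM + 1) of Gb_16563, Novel01102 and Gb_19513 by collection month. Each point is 1 mRNA library (circles number 1, squares number 2) and each bar the mean of 2 libraries. Novel01102 is low in both November libraries, at 0.4 and 0.06 FPKM, and Gb_19513 in both February libraries, at 1.8 and 1.05 FPKM.

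The longest interval, September to February, held the most changed genes. By limma 6218 genes rose and 7782 fell, 61% of those tested, with a median absolute log2 fold change of 1.34. At least 4-fold rises numbered 1525 and 4-fold falls 1804. Gb_19513 fell by 10.26 on the log2 scale (SE 0.61, limma adjusted p = 0.00013). Of the 14000 genes, 2959 passed the threshold in neither successive comparison. Added models accounted for 929 of the genes, 62.7% of the 1482 added models tested, close to the 60.9% of annotated genes. With FPKM as deposited, 349 of these models were higher and 580 lower in February. The median log2 fold change over all tested genes was −0.132, which RLE factors moved by 0.129 and TMM factors by 0.115. With those factors 50.1% and 49.5% of called genes were higher in February, against 44.4% with FPKM as deposited.

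Changes before and after November were compared gene by gene. Of 3130 genes past the limma threshold in both successive comparisons, 1823 went on in the same direction and 1307 (41.8%) turned back. Genes that rose in both numbered 800, against 621.3 expected of independent lists, and genes that fell in both 1023, against 826.1. Genes that rose and then fell numbered 897, against 755.5. Genes that fell and then rose, as Novel01102 did, numbered 410, against 679.4. Both comparisons contain the November libraries. In 50 simulations of unchanged months the median correlation of the fold changes across genes was −0.501, and the observed value was 0.062. The covariance was 0.067 against −0.044 in the simulations, a difference of 0.111. The simulations called a median of 0 genes in both comparisons. They therefore give no reference for the 41.8% or for the counts by direction. The November libraries were not split, since each part would hold 1 library. Sharing them pulls the fold changes toward opposite signs, as in the simulations, so part of the excess of genes that rose and then fell may come from it. Without September 1, 50.9% of the genes turned back.

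In the small-RNA libraries, miR159, which targets MYB transcripts in other plants, held the largest mean share of counts in September and November. It took 47% ± 0.781 in September, 45% ± 7.62 in November and 37.9% ± 3.66 in February (SD, n = 3). In February the mean share of miR166 was larger. miR166, which targets class III homeodomain-zipper transcripts in other plants, held 27.2% ± 7.83, 30.5% ± 4.88 and 43.5% ± 12.6. miR319, which targets TCP transcripts in other plants, held 12.3% ± 3.88, 12.3% ± 5.37 and 3.84% ± 2.16. Over all 9 libraries the 5 most abundant names were pta-miR159a with a mean of 20.9% of counts, gma-miR166u with 6.55%, sof-miR159c with 6.15%, pta-miR159c with 4.79% and mdm-miR159a with 4.52%. The mean of gma-miR166u was below that of sof-miR159c in September (5.23% and 6.22%) and November (5.89% and 6.45%), and above it in February (8.52% and 5.79%). Names of 1 family can list the same reads, so shares of single names are uncertain, and the sums of families can count such reads more than once. The libraries numbered 3 stood apart in every month. The first principal component, 67.3% of variance, was explained to 97.7% by the number and to 1.95% by the month. Component 2, 16.6% of variance, was explained to 38.9% by the number and to 11.4% by the month. It was highest in the libraries with the fewest counts, November 2 (12.48, 90008 counts) and February 3 (12.35, 149187 counts). It was negative only in libraries with 476060 counts or more, and whether depth set it was not tested.

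**Figure D2:**
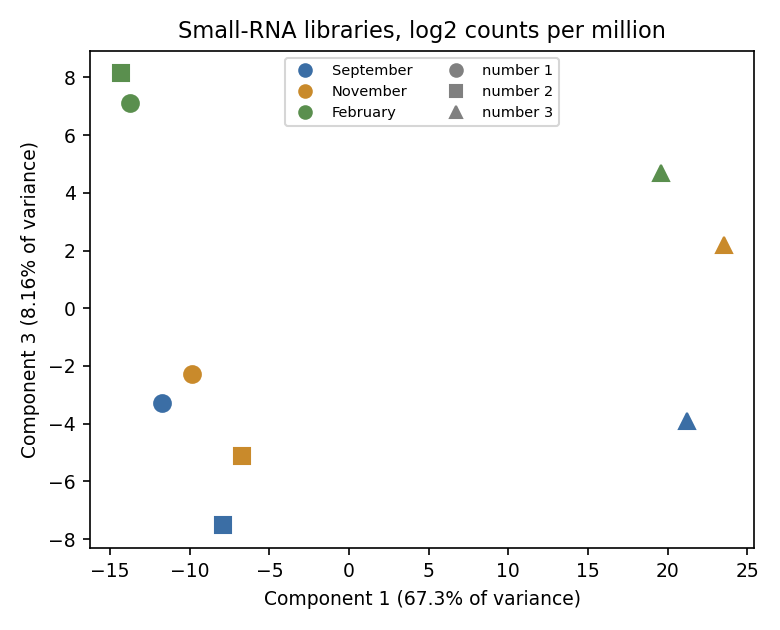
Position of the 9 small-RNA libraries on components 1 and 3 of log2 CPM over 145 miRNA names, with colours for months and shapes for library numbers. The 3 libraries numbered 3 lie apart along component 1, which holds 67.3% of variance, and component 3, which holds 8.16%, was explained to 83% by the month. Component 2, which holds 16.6%, is not shown.

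Between September and November no miRNA name and no family passed the threshold. With edgeR, 0 of 145 names were called, 2 had an unadjusted p under 0.05, and DESeq2 called 0. With the replicate block edgeR called 0, and 5 had an unadjusted p under 0.05. Of 35 families edgeR called 0, with 1 at an unadjusted p under 0.05, and 0 with the block, as did DESeq2. The miR319 family differed by −0.13 (SE 0.4, edgeR adjusted p = 0.89). The miR396 family, which targets growth-regulating factor transcripts in other plants, was lower in 3 of 3 numbered pairs, at −1.11 (SE 0.46, edgeR adjusted p = 0.88). It was singled out after its values were seen.

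Between November and February the miR319 family was lower in 3 of 3 pairs. Its log2 fold change was −1.75 (SE 0.41, edgeR adjusted p = 0.061), and with the replicate block −1.73 (SE 0.27, edgeR adjusted p = 0.013). It was past the threshold when adjusted over the list alone, the only 1 of the 20 fixed families that was, with or without the block. Over all 35 families edgeR called 0, with 2 at an unadjusted p under 0.05, and 1 with the block, while DESeq2 called 1. Among single names edgeR called 0, with 5 at an unadjusted p under 0.05, and with the block 0, with 14 at an unadjusted p under 0.05. DESeq2 called 4 names, with ath-miR319a, mtr-miR319a-3p and ppt-miR319a lower and novel_15 higher in February. The call of miR319 with the block was kept in 3 of 9 fits with a library left out, those without September 1 (adjusted p = 0.043), September 3 (adjusted p = 0.03) or February 3 (adjusted p = 0.0074). It was kept in 4 of 11 other alternatives with the block, and lost with total counts only (adjusted p = 0.16), upper quartile scaling (0.3), no filter on low counts (0.48), DESeq2 (0.093), only the 2 months compared (0.33), libraries numbered 3 left out (0.1) and the strongest name (0.12).

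Between September and February the miR319 family fell in 3 of 3 pairs, from 123500 ± 38800 to 38360 ± 21600 CPM (SD, n = 3). The log2 fold change was −1.88 (SE 0.41, edgeR adjusted p = 0.039), and it was the only family called of 35 tested. With the replicate block 3 families were called. These were miR319 at −1.89 (SE 0.27, edgeR adjusted p = 0.0078), miR2950 at −1.88 (SE 0.4, edgeR adjusted p = 0.035) and miR11534 at −1.64 (SE 0.36, edgeR adjusted p = 0.035). Without the block the adjusted p was 0.53 for miR2950 and 0.16 for miR11534. Adjusted over the list alone, 1 of the 20 fixed families was called without the block and 2 with it. The miR319 call without the block was lost with total counts only (adjusted p = 0.19), upper quartile scaling (adjusted p = 0.078) no filter on low counts (adjusted p = 0.22), the strongest name of the family (adjusted p = 0.071) and libraries numbered 3 left out (adjusted p = 0.09), and its adjusted p over 12 alternatives was 0.0065 to 0.22. It was past the threshold in 2 of 9 fits with a library left out, those without November 3 (adjusted p = 0.034) or February 3 (adjusted p = 0.035). With the block, miR319 passed in 5 of 9 such fits, those without September 1, September 3, November 2, November 3 or February 3, miR2950 in 2 (without September 1 or February 3) and miR11534 in 1 (without February 3). Of 11 other alternatives with the block, the calls were kept in 7 for miR319, 6 for miR2950 and 5 for miR11534. All 3 were lost with total counts only, no filter on low counts, only the 2 months compared and libraries numbered 3 left out (adjusted p = 0.073 to 0.16), miR2950 and miR11534 also with the strongest name (0.11 and 0.09) and miR11534 with upper quartile scaling (0.058). DESeq2 with the block called 5 families higher and 3 lower.

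**Figure D3:**
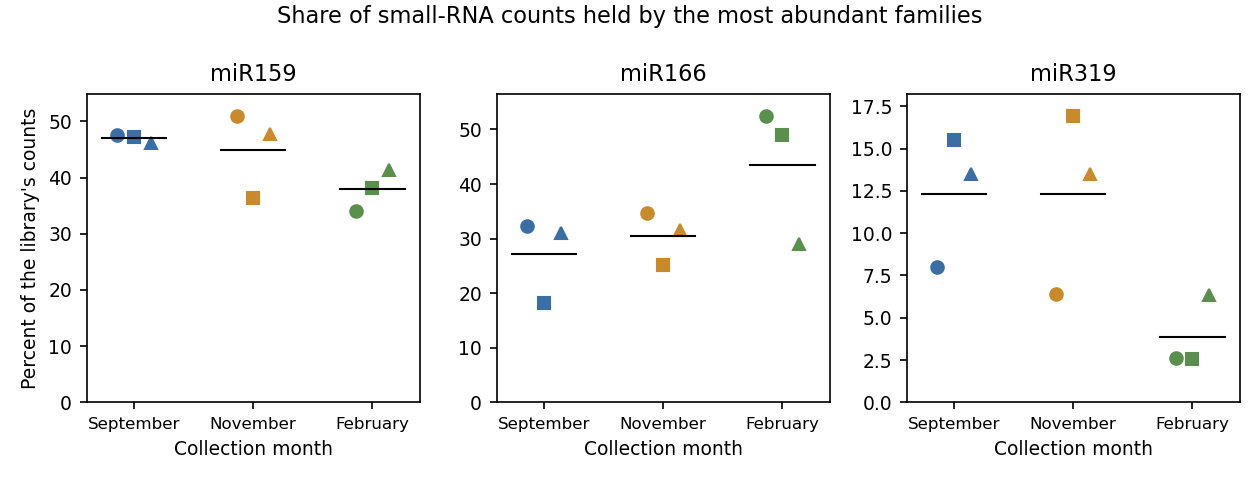
Share of a library's counts listed under miR159, miR166 and miR319, by collection month, with a separate axis from 0 for each family. Each point is 1 small-RNA library, with circles, squares and triangles for numbers 1, 2 and 3, and each bar is the mean of 3 libraries. The mean share of miR319 was 12.3% in September and in November and 3.84% in February.

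Single names in the same comparison gave no call without the block. By edgeR 0 of 145 passed, 7 had an unadjusted p under 0.05, and DESeq2 called 5. With the block edgeR called 5 names, 4 lower and 1 higher in February, but other fits with the block gave more higher than lower names (12 and 9 with DESeq2, 15 and 11 with number 3 left out, 10 and 5 without November 3). The lower ones were ppt-miR319a at −3.08 and vvi-miR2950-5p at −2.39 (edgeR adjusted p = 0.033 for both), and gma-miR319c and gma-miR319q, whose counts were nearly identical, at −2.01 (edgeR adjusted p = 0.037). The higher one was the predicted miRNA novel_15 at 2.7 (edgeR adjusted p = 0.033), from 104.9 ± 30.2 to 707 ± 51.2 CPM (SD, n = 3). With the block and a library left out, each of these 5 names passed without November 3 or February 3, ppt-miR319a also without November 2 and novel_15 also without February 2, and in no other such fit. Of 10 other alternatives with the block, ppt-miR319a and vvi-miR2950-5p passed in 9, novel_15 in 8 and the gma names in 6. The call was lost with total counts only for ppt-miR319a, only the 2 months compared for vvi-miR2950-5p, no filter or upper quartile scaling for novel_15, and all 4 of these for the gma names. DESeq2 without the block called ath-miR319a, mtr-miR319a-3p and ppt-miR319a lower and novel_15 and ppt-miR529e higher. No name passed the edgeR threshold in both successive comparisons, so direction over time could not be given for miRNAs.

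Families that did not pass the edgeR threshold between September and February included miR156 and miR529, which target squamosa promoter-binding protein transcripts in other plants. These were singled out after their values were seen. miR156 was higher in 3 of 3 pairs, at 1.18 (SE 0.79, edgeR adjusted p = 0.53), and miR529 was higher in 3 of 3 pairs, at 3.79 (SE 1.25, edgeR adjusted p = 0.16). Agreement of 3 pairs did not mark out a family. miR164 was also higher in 3 of 3 pairs, at 0.58 (edgeR adjusted p = 0.76), and miR162 lower in 3 of 3, at −0.18 (edgeR adjusted p = 0.84). The adjusted p of miR529 was 0.028 with DESeq2, 0.035 with only the 2 months compared and 0.034 without November 3. Its range was 0.028 to 0.32 over 12 alternatives and 0.034 to 0.46 with a library left out. miR159 differed by −0.45 (SE 0.41, edgeR adjusted p = 0.6) and miR166 by 0.56 (SE 0.56, edgeR adjusted p = 0.62), with TMM scaling. As a share of counts, miR159 was lower in all 3 February libraries than in any September library, which chance gives in either direction for 10% of comparisons of 3 libraries with 3, and the shares of miR166 overlapped between these months.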

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

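The tests with TMM scaling of mRNA, edgeR on recovered reads, libraries numbered 3 left out, identical names counted once, the strongest name of a family and all alternatives with the block were chosen after seeing the data. DESeq2 was planned, and its use on recovered reads was decided after seeing the data. Where no reason is given, the cause was not tested.

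The mRNA counts stayed within 1.5 times of 6990, 9462 and 14000 under the pseudocount, filter, scaling and tool alternatives. DESeq2 on recovered reads gave 7070, 9565 and 13282, and edgeR gave 6192, 9152 and 13258. A threshold of at least 2-fold lowered the counts by construction, to 4574 between September and November, 5907 between November and February and 9964 between September and February. With a single library left out, which assumes that the lone library of a month varies like the other months, the ranges were 2027 to 7143, 3995 to 9287 and 9904 to 15032. The mRNA library numbers did not pair, with correlations of deviations of −0.0858, −0.175 and 0.0979, and the replicate block gave 5768, 8215 and 13110 genes. The share of genes that turned back, 41.8%, was 39.6% with a pseudocount of 0.1, 44.3% with no filter, 38.1% with DESeq2, 39% with edgeR, 44.6% with the 2-fold threshold and 40.5% to 50.9% with a library left out. Of 180 values of named genes under alternatives, 176 kept their side of the threshold and 4, all of Gb_16563, did not. Leaving out a library turned the sign of Gb_19513 between September and November (−1.89 to 0.15) and of Novel01102 between September and February (−0.63 to 0.73), neither past the threshold with all libraries. Calls were gained for Gb_19513 between September and November without November 1 (adjusted p = 0.0056), and between November and February without February 2 for the abundant genes on scaffolds 1909 (1900883 to 1902638, adjusted p = 0.028) and 9952 (adjusted p = 0.023).

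Without the block, miRNA name counts moved from 0 only with DESeq2, to 4 for February against November and 5 for February against September, with the replicate block, to 5 for February against September, and without November 3, to 1 (range 0 to 1). Family counts for February against November were 1 with 100 counts as the minimum, DESeq2, RLE scaling, identical names counted once and the replicate block, and 0 to 1 with a library left out. For February against September they were 3 with the replicate block, 2 with DESeq2 and with only the 2 months compared, 0 with number 3 left out, no filter, the strongest name, total counts only and upper quartile scaling, and 0 to 2 with a library left out. The block changed no other call.

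Within pairs, name counts for February against September were 11 with 100 counts as the minimum, 21 with DESeq2, 26 with number 3 left out, 3 with only the 2 months compared, and 2 each with no filter, total counts only and upper quartile scaling. They were 0 to 16 with a library left out, with 15 without November 3 and 16 without February 3. For February against November they were 4 with 100 counts as the minimum, 5 with DESeq2, 12 with number 3 left out and 0 to 7 with a library left out, and for November against September 1 with number 3 left out. Family counts within pairs for February against September were 8 with DESeq2, 1 with the strongest name, 0 with number 3 left out, no filter, only the 2 months compared and total counts only, and 0 to 6 with a library left out. For February against November they were 0 under those 6 alternatives and upper quartile scaling, and 0 to 1 with a library left out. The fold change of miR319 within pairs for February against September stayed between −3.08 and −1.71 over 11 alternatives, 7 of them past the threshold, and between −2.01 and −1.21 with a library left out, 5 of 9 past it. Without the block, leaving out a library turned the sign of gma-miR319c and gma-miR319q (−4.48 to 0.67) and of miR319 for November against September (−0.4 to 0.11).

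The planned set tests and their alternatives were not run, since no gene descriptions were at hand, and a pseudocount does not apply to counts. November 2 held the fewest small-RNA counts, 90008, in which a count of 0 allows up to 33.3 CPM. Leaving it out raised no count of miRNA names or families called, with or without the block.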

Other observations

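The tests on reads shared with miR159, on a single name, on names of the same family, on a library batch and on neighbouring genes were chosen after the result was seen, and the test on names of the same family was split by month after a test over all months was undecided.

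Genes switched between near absence and abundance were few. Genes at 0.5 FPKM or less in both libraries of a month and at 10 FPKM or more in the other 4 libraries numbered 8 for September, 1 for November and 11 for February. Genes at 10 FPKM or more in a single month and at 0.5 FPKM or less in the other 4 libraries numbered 10, 1 and 12. In November 1 alone, 4 genes were listed at 0.1 FPKM or less while all other libraries held 10 FPKM or more, and no other library had such a gene. The genes on scaffolds 689, 3202 and 3621 among them were listed at 0 in November 1 and at 424.1, 479.4 and 484 FPKM in November 2. The ratio between any pair of these 3 genes varied by at most 1.22 times over the other 5 libraries, and they differed between the September libraries too, at 19.44 to 19.9 and 200.5 to 232.5 FPKM. The fourth gene, on scaffold 2536, was also at 0 in November 1, and its ratios to the other 3 varied by 6.77 to 7.83 times.

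Within the miR319 family 8 names were tested, and 6 were lower and 2 higher in February than in September within pairs. Shared reads with miR159, whose sequence is close to that of miR319, would lower both families if they were lost. The log2 change of miR159 would then be the smaller, since its share of counts was larger. The log2 change of miR319 minus that of miR159 was −1.46 (SD 0.73, n = 3 pairs), so the families did not change in proportion. Between September and February the mean share of miR159 fell from 47% to 37.9% and that of miR319 from 12.3% to 3.84%. Sharing therefore stays open. Without ppt-miR319a, the name with the largest fall, the fold change of the family within pairs was −1.32 (SE 0.41, edgeR adjusted p = 0.13), against −1.89 (SE 0.27) with it. That value lies more than 2 SE below 0, so this name as listed did not account for the whole change. The call ended because the change was smaller and its SE larger. Names of a family can list the same reads, so a change of a single sequence stays open. Thinning all libraries to 90008 counts gave a median of −1.6 over 20 draws (range −1.82 to −1.4), past the threshold in 2 draws. The size moved by slightly more than its SE, so a part played by unequal depth stays open. Each thinned set was also filtered and scaled anew, so depth cannot be told from a changed set of names or changed TMM factors. The lost call may come from any of these or from the counts that thinning removed, which this test cannot tell apart. A change with the month stays open.

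After thinning to equal totals, the highest correlation of a small-RNA library numbered 3 with the others was 0.706 in the median of 20 draws. The lowest correlation among libraries numbered 1 and 2 was 0.83, likewise a median over draws. That gap argues against depth. Whether listing of the same reads under other names of a family accounts for the separation in September and November could not be decided. Summed by family, the libraries numbered 3 differed in those months from the others in at most 18.8% of counts. Those numbered 1 and 2 differed from each other in 14.7% in September and 24.2% in November. Such shares are set mostly by the most abundant families, while the separation was seen on log2 CPM across names, abundant or not. In February the lowest difference from number 3 was 24.2%, against 5.62% between numbers 1 and 2, which argues against such listing as the whole cause there. A library batch stays open, since the number explained 97.7% of component 1 and the labels give no batch, and no biological explanation was tested.

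Neighbouring genes changed together between September and February, up to 1 Mb apart on the same strand and up to 100 kb on opposite strands. These are correlations across genes, which are not independent replicates. Same-strand pairs 0.1 to 1 Mb apart correlated at 0.153 (5687 pairs, highest random 0.0291). Opposite-strand pairs at that distance were barely above random pairings (0.0432 against 0.0315). Pairs over 1 Mb apart were within random pairings (0.0396 on the same strand and 0.103 on opposite strands). Overlapping models could share reads, but same-strand neighbours 10 to 100 kb apart correlated at 0.381 (2460 pairs), above the highest of 100 random pairings, 0.0447. Opposite-strand neighbours at that distance correlated at 0.156 (1477 pairs, highest random 0.0506), which argues against the splitting of a gene into several models as the cause for these pairs. Same-strand neighbours up to 10 kb apart correlated at 0.64 (615 pairs) and opposite-strand ones at 0.469 (395 pairs). The same-strand value was also the higher at 10 to 100 kb and at 0.1 to 1 Mb. Splitting may therefore contribute to same-strand pairs at all these distances and stays open for them. Regulation shared by neighbouring genes stays open as a hypothesis, and no group in the design tests it.

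The splits of the 6 small-RNA libraries of a comparison number 10 with the real one included, or 4 that part all pairs, too few for a share under 0.05. For names without the block the real split called 0 in all 3 comparisons and no other split called more, so 10 of 10 splits reached the real count. For families without the block, the real count for November against September was 0 and the highest other 0 (10 of 10), and for February against September it was 1 and the highest other 0 (1 of 10). For February against November it was 0 (10 of 10), and a split with November 1, November 3 and February 1 on 1 side called 6 families. Those are the 3 of these 6 libraries with the most counts, 499758 to 1269029, against 90008 to 376186 in the others, which points to a structure other than the month. Within pairs the other splits exchange the months of a single pair. For names the real and highest other counts were 0 and 0 for November against September and for February against November (4 of 4 each), and 5 and 0 for February against September (1 of 4). For families they were 0 and 0 (4 of 4), 1 and 1 (2 of 4), and 3 and 0 (1 of 4) in the same order.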
